A study of Mus musculus with 425 samples.

How the data were processed

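RNA was measured in 425 single cells from CD-1 mice, captured on C1 microfluidic chips after papain digestion, with a library chemistry that tags the 5′ end of each transcript and counts molecules. The digestion time varied with the size of the tissue piece, per the labels. The table deposited by the authors holds raw counts, whole numbers of unique molecular identifiers (UMIs) per gene and cell with no normalization, for 15741 gene names, of which 14910 had a count in at least 1 cell. The submitters' processing notes give the mouse genome build mm10; the aligner and the counting program are not given in the sources used here. Of the gene names, 14709 matched a RefSeq symbol, which gave the coordinates printed here. The table lists 13970 of 21900 protein-coding symbols, and many abundant genes, such as Actb and most ribosomal protein genes, have no entry, so a cell's total is the sum over the listed genes and not its full depth. Levels are given as CPM, scaled to the sum of those UMIs.

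Totals ran from 729 to 10260 UMIs per cell (median 1995), over 324 to 4561 genes. Shares of cells carry exact Clopper-Pearson intervals and counts carry exact Poisson intervals, both at 95%. These cover counting error alone. A count of 0 is bounded by 3 counts over the group.

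No label gives a cell's class. Cells were grouped by Ward clustering on 57 marker genes alone, scaled to 2000 UMIs and log-transformed, and the tree was divided into 3 clusters that were named from the marker panels. This gave 184 microglia-like cells, 222 perivascular macrophage-like (PVM-like) cells and 19 cells that no panel named. The labels name no animals. Counts of a class were therefore summed into pools of one region and one age in days, since different postnatal days are different animals, while pools of one day from different regions may share animals. For the class comparison, pools were made per day over all regions and the day was a block.

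Tests used edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM scaling, filterByExpr with a minimum count of 10 and total of 15) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Errors of fold changes are standard errors from the F statistic. Pools held at least 3 cells, or 2 in the class comparison and per chip. Marker genes were left out of the class test because they define the classes. The comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The rule takes, among called genes with an average log2 CPM of at least 5, the 6 with the largest positive and the 6 with the largest negative change, and the 2 called members with the smallest p from every biology list. For tests over regions it takes the 12 genes with the smallest p and the leading called member of each list. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with the correlation estimated, where at least 3 members were tested.

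Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter and a stricter filter on low counts, other minimum numbers of cells per pool, cells thinned to 1000 UMIs, pools per chip, all cells whatever their class, classes from 300 variable genes outside the panels, and other covariates. A test of embryonic ventral midbrain chips, a test of regions among the PVM-like cells, and removal of the tenth of cells richest in RNA of other cell types were chosen after seeing the data. Each test was also tested on simulated data with known changes. In those, a log2 change of 3 was recovered for 100% of genes in the class test, 76.9% in the stage test, 66.7% in the chip test, 85.7% in the region test and 57.1% in the PVM-like region test, and a log2 change of 6 over 10 days for 53.8% in the age test. Each share comes from 1 simulation and, outside the class test, from few genes. At a log2 change of 3, the changed genes numbered 65 in the class test and 13 in the stage test. They numbered 3 in the chip test, 7 in the region test and 14 in the PVM-like region test. Smaller changes were often missed. A log2 change of 2 was recovered for 95.0%, 10.0%, 75.0%, 57.1% and 61.5% in the same order, a log2 change of 1 for 34.6%, 16.7%, 25.0%, 33.3% and 0%, and changes of 4 and 2 over 10 days for 27.3% and 0% in the age test. With no change simulated, the tests made 0 or 1 calls. With changes simulated, 7 of 147 calls in the class test, 3 of 15 in the region test and 0 in the others were false. Without the day as a block, 114 of 208 tested genes were called between the classes.

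Left out of the comparisons were 16 cells labelled sscortex, 4 cells from bone marrow and epidermis, and 6 brain cells of days 67 to 90. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for clustering, exact tests and plots. Results of some items withheld for evaluation are not reported here.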

Results

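The series holds 425 cells on 197 chips, which the title describes as microglia and perivascular macrophages found in a survey of mouse brain. Of these, 372 came from postnatal brain of days 16 to 31, 43 carried an embryonic label that spans E11.5 to E18.5, 6 came from older brain and 4 from outside the brain. The postnatal regions were cortex S1 (22 microglia-like, 95 PVM-like and 1 unnamed cell), DentGyr (57 cells), Amygdala (47), hypothalamus (37), ZonaIncerta (36), SN-VTA (28), hippo CA1 (20), sscortex (16), striatum (12) and dorsal horn (1). The embryonic regions were ventral midbrain (25 cells), cortex S1 (11) and dorsal horn (7). Median totals were 2096.5 UMIs in PVM-like cells, 1849 in microglia-like cells and 4135 in embryonic ventral midbrain cells.

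The cells were divided into classes by marker genes. In 11 pools of postnatal microglia-like cells, Tmem119, a membrane protein gene, averaged 969 CPM ± 497 (SD) against 13.1 ± 27.3 in the matched PVM-like pools, and the purinergic receptor P2ry12 3846 ± 2036 against 324 ± 219. The mannose receptor Mrc1 averaged 4996 ± 1377 CPM in PVM-like pools against 67.9 ± 165 in microglia-like pools, and the chemokine Pf4 6815 ± 1943 against 28.5 ± 66.7. F13a1, Cbr2, Ms4a7, Lyve1 and Cd209f had 0 UMIs in the microglia-like pools. Fcrls, listed as a microglia marker, did not separate the classes, with 2141 ± 1174 and 2406 ± 484 CPM, nor did Bin1, with 361 ± 214 and 321 ± 226. These values define the classes and were not tested. Of all cells of both classes, 36 had between 25% and 75% of their panel UMIs from the microglia panel. With classes made from genes outside the panels, 35 PVM-like and 18 microglia-like cells changed class (86.9% agreement).

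Regions differed in their mix of the classes. PVM-like cells made up 80.5% of the cells of cortex S1 (interval 72.2% to 87.2%) and 22.8% of those of DentGyr (12.7% to 35.8%). Per day pool of at least 3 cells, the share was 81.8% ± 10.9 (SD, n = 8) in cortex S1 and 22.6% ± 15.5 (SD, n = 6) in DentGyr, a pair chosen after the shares were seen (two-sided exact permutation test, p = 0.000666). SN-VTA averaged 85.7% ± 24.7 (SD, n = 3) per day pool, but over all its 28 cells the share was 67.9% (interval 47.6% to 84.1%). How many cells of each class were kept for the series is not stated, so these are shares of the cells listed.

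**Figure D1:**
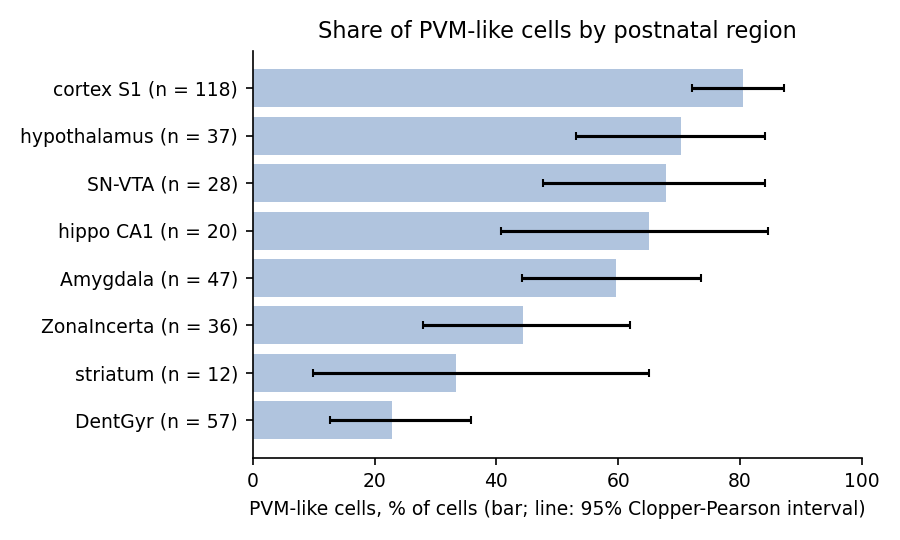
Share of PVM-like cells (%) among the cells of the 8 postnatal regions with cells of both classes, with 95% Clopper-Pearson intervals as lines and the number of cells beside each name. Of these, cortex S1 stands highest at 80.5% and DentGyr lowest at 22.8%.

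The first comparison asked how the transcriptomes of the classes differ beyond the markers that define them. With the classes made from the marker panels, PVM-like cells carried scavenger and lectin receptors that microglia-like cells lacked almost entirely. Clec4n, the C-type lectin Dectin-2 (chromosome 6, 123229843 to 123247024), averaged 879.7 CPM ± 250 (SD, n = 11) and was at least 81.9-fold higher. Cd209g, another C-type lectin, averaged 644 ± 730 CPM and was at least 50.4-fold higher, with 0 UMIs over all microglia-like pools. The fatty acid scavenger receptor Cd36 (chromosome 5, 17781690 to 17888959) had 620 UMIs against 2, a ratio of 172 (counting interval 47.3 to 1420.1). The lysozyme gene Lyz2 rose by 6.09 ± 0.44 on the log2 scale (SE, 11 of 11 day pairs), from 125 to 7885 CPM. These sizes depend on how the classes are made. With classes from genes outside the panels, the log2 differences were 2.01 for Clec4n, 2.65 for Cd209g, 2.72 for Cd36 and 2.49 for Lyz2, all still called by edgeR.

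Among phagocytic and scavenger receptors, 14 of 27 listed genes were tested, 10 were called higher and 1 lower in PVM-like cells. Fcgrt, which recycles antibody and albumin, was higher by 3.98 ± 0.37 (log2, SE) in 11 of 11 pairs. The camera test with Benjamini-Hochberg adjustment gave p = 1.19e-05 for this list, and adjusted p = 0.0515 with an estimated correlation. The embryonic macrophage list had 8 of 9 tested genes higher and 0 lower, led by Cd36, Clec4n and Lyz2 (camera, Benjamini-Hochberg adjusted p = 8.80e-11, and 0.00279 with an estimated correlation). Lipid handling genes were higher in 4 of 6 cases, among them Plin2, a coat protein of lipid droplets, at 3.05 ± 0.43. Iron and heme genes were higher in 5 of 7 cases and lower in 0, among them Blvrb, a biliverdin reductase, at 4.62 ± 0.46, and the ferroxidase ceruloplasmin, Cp, at 5.08 ± 0.57. With camera and Benjamini-Hochberg adjustment the lipid list had p = 0.000105 and the iron list p = 0.000165, and both had adjusted p = 0.0118 with an estimated correlation.

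Microglia-like cells were richer in a different set. Of 13 tested mature microglia genes outside the panel, 9 were lower in PVM-like cells and 2 higher (camera, Benjamini-Hochberg adjusted p = 1.51e-05, and 0.0480 with an estimated correlation). Selplg, the ligand of P-selectin, fell by 3.88 ± 0.36 on the log2 scale in 11 of 11 pairs, and the protease gene Ctss fell by 1.99 ± 0.20, from 9625 to 2212 CPM. Tgfbr1, a TGF-beta receptor, fell by 3.41 ± 0.36 and the integrin Itgam by 3.21 ± 0.35, both in 11 of 11 pairs. Gal3st4, a sulfotransferase, fell by 4.51 ± 0.67 and Lhfpl2 by 4.15 ± 0.63. Gpr84, a receptor for medium-chain fatty acids, had 97 UMIs in microglia-like pools and 3 in PVM-like pools, a ratio of 0.0171 (counting interval 0.00347 to 0.0515). Lat2 and the calpain Capn3 had ratios of 0.0268 (0.00538 to 0.0820) and 0.0226 (0.00266 to 0.0861).

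Signalling genes were divided between the classes. Of 18 tested cytokine and NF-kB genes, 8 were lower and 4 higher in PVM-like cells (camera, Benjamini-Hochberg adjusted p = 0.0602). Il1a, an interleukin-1 gene, fell by 3.54 ± 0.38 and the survival gene Bcl2a1b by 2.38 ± 0.30, both in 11 of 11 pairs. The neutrophil chemokine Cxcl1 was higher by 5.53 ± 0.56, and the cytokine Tslp had 188 UMIs against 2, a ratio of 52.03 (14.2 to 433). Of 5 tested interferon genes, 3 were higher, among them Ifi27l2a at 4.07 ± 0.50 and Ifitm3 at 2.73 ± 0.45 (camera, Benjamini-Hochberg adjusted p = 0.0371, and adjusted p = 0.0878 with an estimated correlation). In the disease-associated or axon-tract list, 5 of 11 were higher and 3 lower (adjusted p = 0.172, camera with Benjamini-Hochberg), with the growth factor Igf1 higher by 4.93 ± 0.56 and the galectin Lgals1 by 3.83 ± 0.45. Other genes higher in PVM-like cells were properdin, Cfp, at 4.68 ± 0.55, cathepsin C, Ctsc, at 2.36 ± 0.28, the complement receptor C5ar1 at 2.51 ± 0.40 and the transcription factor Maf at 2.23 ± 0.26. Of the complement list 3 of 9 genes were higher and 2 lower, of the lysosome list 7 of 16 and 2, of the purine and chemokine receptors 4 of 7 and 2, and of the TGF-beta and transcription factor list 2 of 11 and 4. Of 4 glycolysis genes 0 were called by edgeR.

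Genes of the dissociation response went both ways, with 7 of 19 higher and 3 lower. The heat shock gene Hspa1b was higher by 3.06 ± 0.46 in 9 of 11 pairs and Rgs1, a regulator of G protein signalling, fell by 3.54 ± 0.50 in 11 of 11. The summed dissociation list was 15547 CPM ± 4864 in microglia-like and 14596 ± 3455 in PVM-like pools. The oligodendrocyte list, RNA of another cell type, summed to 24683 ± 22211 and 32639 ± 29846 CPM, higher in PVM-like cells in 8 of 11 pairs. These day pools mix regions, in which the share of each class differs. By region, the list was higher in microglia-like cells of cortex S1 (94763 against 65622 CPM), ZonaIncerta, hippo CA1 and striatum. It was higher in PVM-like cells of Amygdala, DentGyr, SN-VTA and hypothalamus. Its camera test had an adjusted p of 0.0417 (Benjamini-Hochberg), and adjusted p = 0.543 with an estimated correlation. The mural or fibroblast list summed to 388.1 ± 588 and 1129 ± 1001 CPM, higher in PVM-like cells in 11 of 11 pairs, with Dcn and Acta2 called among 3 genes tested (camera, Benjamini-Hochberg adjusted p = 0.176).

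In total, edgeR tested 1448 genes in 11 day pairs of pools (349 cells, 2199 to 117328 UMIs per pool) and called 317 at a Benjamini-Hochberg adjusted p under 0.05, 190 higher and 127 lower in PVM-like cells. Adjusted over the list alone, counts were the same as over all genes for the mature microglia (11), embryonic macrophage (8) and iron (5) lists, and changed from 11 to 12 for the phagocytic list, from 8 to 9 for the axon-tract list and from 6 to 9 for the TGF-beta list. Calls fell to 144 of 328 genes tested with pairs of one region and one day, a setting added after seeing the data.

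**Figure D2:**
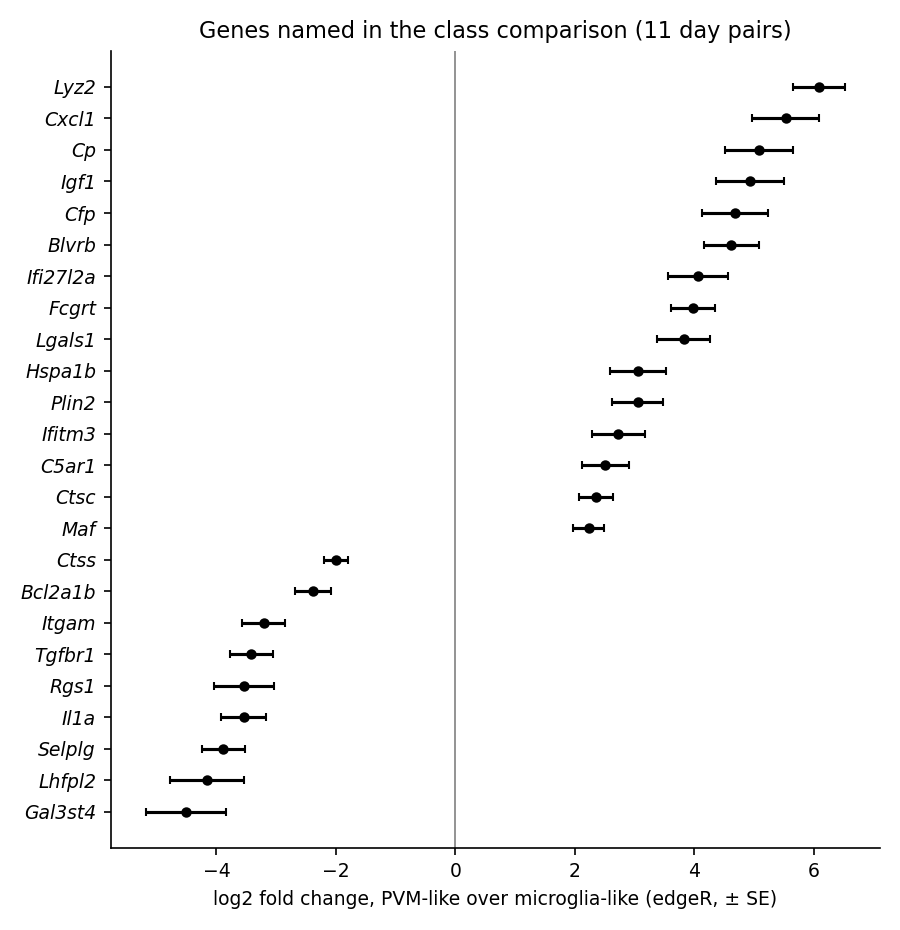
Log2 fold change of PVM-like over microglia-like cells with its standard error (edgeR, 11 day pairs) for the named genes with over 3 UMIs in both classes. Lyz2 stands highest at 6.09 and Gal3st4 lowest at -4.51.

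The second comparison asked how embryonic microglia-like cells differ from postnatal ones. The embryonic pools did not resemble each other. In the ventral midbrain pool (25 cells), Spp1, which encodes osteopontin, stood at 6835 CPM (interval 6377 to 7317), and the mitosis gene Top2a at 1215 (1027 to 1428). Neither gene had a UMI in the embryonic cortex S1 pool (5 cells) or dorsal horn pool (7 cells), which allows up to 278 and 181 CPM. Tmem119 was 215 CPM (140.4 to 315) in the ventral midbrain, 1759 (1059 to 2747) in cortex S1 and 905 (507 to 1493) in dorsal horn, beside 1047 ± 462 (SD, n = 22) in the postnatal pools. The myelin glycoprotein gene Mog was 5734 CPM (4639 to 7009) in dorsal horn and had 0 UMIs in the other embryonic pools. Cell cycle genes of mitosis summed to 6976, 92.6 and 181 CPM in ventral midbrain, cortex S1 and dorsal horn. The radial glia or neuroblast list, RNA of other cell types, summed to 6182, 926 and 1147 CPM in the same pools. In postnatal pools that list averaged 808 ± 654 (SD, n = 22). Which cells the mitosis RNA came from was not tested.

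Between the 3 embryonic and 22 postnatal pools (152 cells, 156 genes tested) edgeR called 0 genes, with 12 at an unadjusted p under 0.05, and DESeq2 called 0, with 11 at an unadjusted p under 0.05. In the camera test with Benjamini-Hochberg adjustment, 3 of 11 lists passed at the preset correlation and 0 with an estimated correlation. The axon-tract list was higher (adjusted p = 0.0215, and adjusted p = 0.180 with an estimated correlation), as was the phagocytic list (adjusted p = 0.0383, and adjusted p = 0.267 with an estimated correlation). The dissociation list was lower (adjusted p = 0.0383, and adjusted p = 0.599 with an estimated correlation), with a median log2 change of -0.05 and a mean of 0.15, which differ in sign. With cells of any class, 2 genes were called, named after their values were seen, Spp1 at 5.26 ± 0.77 and the cell cycle kinase Cdk1 at 3.98 ± 0.72. Without a filter on low counts 316 genes were called, and with cortex S1 and midbrain regions alone 10. The embryonic pools may share animals.

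**Figure D3:**
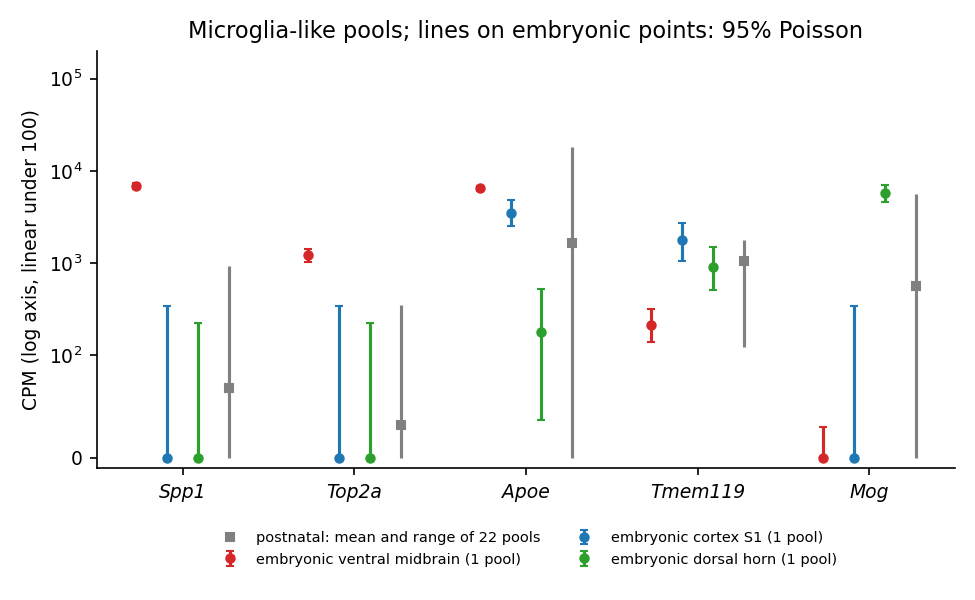
CPM of 5 genes in the 3 embryonic microglia-like pools (points with 95% Poisson intervals) and in 22 postnatal pools (squares for the mean, lines for the range). Spp1 and Top2a are high in the ventral midbrain alone among the embryonic pools, and Mog is highest in dorsal horn at 5734 CPM.

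Because the ventral midbrain stood apart, its cells were compared by chip with postnatal cells, a test chosen after seeing the data. All embryonic chips in it were of ventral midbrain, while postnatal midbrain entered only as SN-VTA, with 2 cells. Stage and region therefore cannot be told apart in this test. Digestion time, which varied with the size of the tissue piece, was not part of it. The apolipoprotein gene Apoe was higher by 3.34 ± 0.60 on the log2 scale, at 7103 CPM ± 3464 (SD, n = 6 chips) against 704 ± 1221 (n = 30). The protease gene Ctsz was higher by 1.74 ± 0.39, Aif1, which encodes the microglial protein Iba1, by 1.25 ± 0.37, the selenoprotein gene Sepp1 by 1.20 ± 0.30, the adaptor Tyrobp by 1.03 ± 0.24, Ly86 by 0.88 ± 0.31 and the complement gene C1qb by 0.71 ± 0.27. Sparc, a matricellular protein of mature microglia, fell by 1.18 ± 0.30. All 4 tested dissociation genes fell, Ier5 by 2.65 ± 0.76, Btg2 by 2.36 ± 0.70, Rgs1 by 2.30 ± 0.90 and Zfp36 by 2.15 ± 0.49, and the NF-kB inhibitor Nfkbia fell by 3.28 ± 0.54.

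In this test edgeR called 15 of 44 genes at a Benjamini-Hochberg adjusted p under 0.05, 7 higher and 8 lower (87 cells). The axon-tract and dissociation lists passed camera, with adjusted p of 0.0210 and 0.0222, and both had adjusted p = 0.0241 with an estimated correlation. Chips of one region may share animals, so the spread between chips is not that between animals. With at least 3 cells per chip, 13 of 13 named genes that were tested lost their call, and the 3 genes called instead were Spp1 at 6.22 ± 1.06, Nnat at 4.70 ± 1.09 and Tubb3 at 3.41 ± 0.75, named after their values were seen.

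The third comparison asked whether microglia-like cells differ between postnatal regions. Cells of DentGyr carried transcripts of neurons and astrocytes. Adcy1, a neuronal adenylate cyclase, averaged 1440 CPM ± 619 (SD, n = 6) with 120 UMIs, and had 0 UMIs in the pools of Amygdala (n = 4) and ZonaIncerta (n = 4). The neuronal kinase gene Camk2a averaged 1627 ± 411 CPM in DentGyr, 431 ± 122 in Amygdala and 167 ± 210 in ZonaIncerta. The postsynaptic gene Nrgn averaged 1085 ± 408, 390.0 ± 238 and 30.5 ± 61, and the astrocytic glutamate transporter Slc1a2 1527 ± 698, 168 ± 211 and 91.5 ± 183. Camk2b, D3Bwg0562e, the ephrin receptor Epha4 and the glutamate receptor Gria1 were highest in DentGyr too. Neuronal RNA was not particular to DentGyr. Summed over microglia-like cells, the neuron list was 4224 CPM in hippo CA1 and 3996 in striatum, both outside this test, against 3344 in DentGyr.

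Genes of microglia themselves did not pass the threshold in these pools. Olfml3, a panel gene, averaged 1528 ± 1108 CPM in Amygdala, 72.4 ± 73.1 in DentGyr and 381 ± 188 in ZonaIncerta, with an edgeR Benjamini-Hochberg adjusted p of 0.0910. The complement gene C1qc had an adjusted p of 0.0746, Epb4.1l2 of 0.0783 and the transcription factor Zfhx3 of 0.137 (edgeR, Benjamini-Hochberg). Of 15 tested mature microglia genes, 0 were called by edgeR. Adjusted over the list alone, 1 complement gene and 1 phagocytic receptor passed. The summed neuron list was 3333 CPM ± 836 in DentGyr, 2214 ± 1441 in Amygdala and 1852 ± 985 in ZonaIncerta. The dissociation list was 9411 ± 1846, 16386 ± 4744 and 12390 ± 3719.

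The edgeR test over 3 regions, with age in days as a covariate (14 pools, 79 cells, 91 genes), called 8 genes at a Benjamini-Hochberg adjusted p under 0.05, with 18 at an unadjusted p under 0.05. DESeq2 called 11, adding Olfml3, C1qc and Epb4.1l2, and cells thinned to a common number of UMIs gave 0 calls among 21 genes. With chips as pools, which added cortex S1 as a region, edgeR called 12 of 63 genes, among them the cytokine genes Ccl2 and Il1a and the activation gene Cd83 (Benjamini-Hochberg adjusted p = 0.00267, 0.00267 and 0.0129), named after their values were seen. Amygdala pools were of days 26 to 29 and the others of days 19 to 25, so region and age are confounded there and are separated only by an assumed linear trend.

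**Figure D4:**
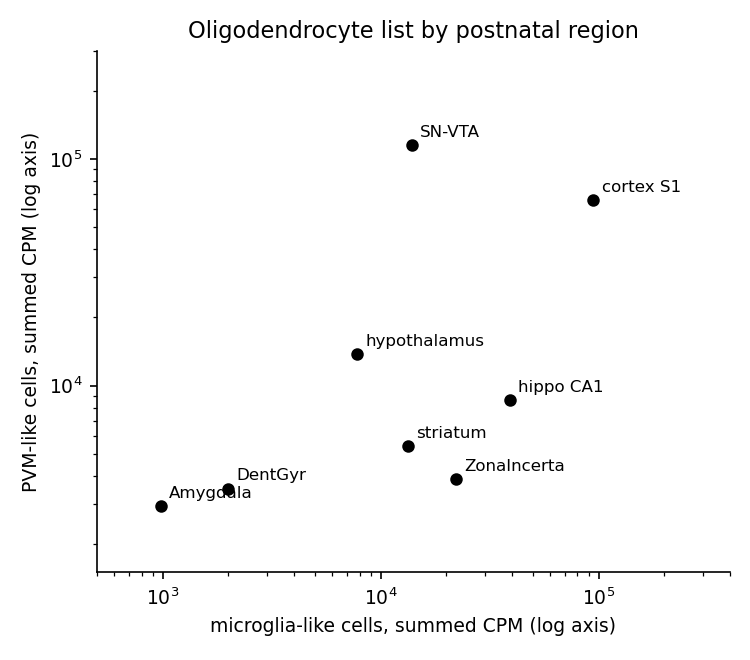
Summed oligodendrocyte list (CPM, log axes) in microglia-like and PVM-like cells of the 8 postnatal regions with at least 4 cells of each class. It ranges from 980.1 CPM in Amygdala to 94763 in cortex S1 among microglia-like cells.

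The last comparison asked whether microglia-like cells change with postnatal age. The largest evidence was for Cx3cr1, the fractalkine receptor, at 0.18 ± 0.08 log2 units per day with an edgeR Benjamini-Hochberg adjusted p of 0.996. In 20 pools of 6 regions (165 genes), edgeR called 0 genes, with 1 at an unadjusted p under 0.05, and DESeq2 called 0, with 4 at an unadjusted p under 0.05. No list passed camera among 11 tested. Each of 2 other settings called 1 gene, named after its value was seen. The chemokine Cxcl10 fell by 1.16 ± 0.22 per day with at least 5 cells per pool, and the myelin gene Mal was higher by 1.24 ± 0.22 per day within days 20 to 29.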

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

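All tests below were chosen after the result was seen, except the correlation test of the cells with the embryonic label.

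The 16 cells labelled sscortex, used in no comparison, looked like no other cell of the table. Gen1 reached 68260.2 CPM, all 4098 UMIs in 1 cell, while Ctss, Cx3cr1 and B2m had 0 UMIs in all 16. Of these cells, a median of 3.12% had a UMI, taken over 54 genes. Those genes were found in at least 50% of the cells of each class and source. That does not exclude cells of another type. Both classes are macrophage-like, and the 2 epidermis cells were classed PVM-like, so another type may lack these genes too. Low totals are argued against, with a median of 3286.5 UMIs in the sscortex cells against 1969 in the other cells of both classes. Genes of chromosome 12 held a median of 27.2% of their UMIs (14.8% to 61.99%) against at most 6.40% in any other cell. Gene names out of step with the counts in these columns may account for this. Their order was not restored here, so the cells were left out.

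The cortex S1 and dorsal horn microglia-like cells with the embryonic label looked unlike the ventral midbrain cells with the same label. Over 2297 genes outside the lists of other cell types, their summed profile correlated more with postnatal cells than with ventral midbrain cells, by 0.132 (bootstrap interval 0.0229 to 0.235). An age label that is not that of the cells may account for this, though this is 1 test across genes, which are not independent. The 6 PVM-like cells of cortex S1 with the same label point the other way. Their mitosis genes summed to 4492 CPM in 1 pool, against 316 ± 282 (SD, n = 27) in postnatal PVM-like pools. All 8 of their Top2a UMIs lay in 1 cell. Oligodendrocyte RNA on top of cells like those of the ventral midbrain is argued against by the mitosis genes. In the 12 microglia-like cells of cortex S1 and dorsal horn, these had an upper limit of 374 CPM where 5950 was needed. The limits cover counting error alone, not the spread between cycling and other cells. A difference between embryonic regions stays open and cannot be told apart from a wrong label, because all 3 regions share 1 label with no days.

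Oligodendrocyte RNA was found in both classes and varied by region, from 980.1 CPM in Amygdala to 94763 in cortex S1 among microglia-like cells. RNA of other cells caught with a cell may be the source, but the rank correlation between the classes over 8 regions was 0.619 (exact permutation p = 0.115, Benjamini-Hochberg adjusted over 4 relations 0.230; Pearson r 0.570, permutation p = 0.132, adjusted 0.264), and r was 0.194 without Amygdala and cortex S1. Oligodendrocytes caught whole with some cells stay open. RNA taken up by the cells in the tissue was not testable in these 8 regions and cannot be told apart from the others. The same test gave a rank correlation of 0.452 for the neuron list, 0.00 for the dissociation list and 0.667 for Ccl3 with Ccl4 (exact permutation p = 0.267, 1 and 0.0831).

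In several groups of 4 to 10 pools, 1 pool lay far from the others in a value reported here. This was found 19 times in 130 groups, where chance gives about 1 in 20. In 7 of the 19 all other pools had 0 UMIs, so that any count stands out and this rate does not hold. In microglia-like cells, the DentGyr pool of day 25 had the highest C1qc, at 1832 CPM, and the highest oligodendrocyte list, at 4224. The ZonaIncerta pool of day 19 had an oligodendrocyte list of 65268 CPM, Slc1a2 at 366 and Nrgn at 122, with 0 for both genes in the other ZonaIncerta pools, and its C1qc was lowest, also at 122. In PVM-like cells of Amygdala, the pool of day 21 was highest in Car2, at 385 CPM, and Mobp, at 193, and the pool of day 29 in Mal, at 129, and Nnat, at 1033. In PVM-like cells of cortex S1, the pool of day 31 had the highest Apod, at 11776 CPM, that of day 21 the highest Nnat, at 70.3, and that of day 28 the highest Fcer1g, at 2999, and C1qb, at 6223. In PVM-like cells of the hypothalamus, the pool of day 21 was highest in Car2, at 189.7 CPM, and Mog, at 284, and that of day 27 in Nnat, at 3662. Among the 6 embryonic ventral midbrain chips, 1 had Tyrobp at 8749 CPM against at most 4301 in the others, and another had Btg2 at 1109.9 CPM.

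Other cells outside the comparisons carried genes that brain cells of both classes had at low levels. Plac8, a gene of monocytes, reached 6157 CPM in the 2 bone marrow cells. The keratin gene Krt15 reached 4442 CPM in the 2 epidermis cells. Cd74, the invariant chain of MHC class II, reached 2585 CPM in the 6 brain cells of days 67 to 90, with all 20 UMIs in 1 cell.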

How the results depend on the processing

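Of the values below, those with region-day pairs, ventral midbrain alone, PVM-like regions and chips as the main test, and without other-cell genes or cells were chosen after seeing the data. The class comparison gave 301 to 411 calls, 221 to 317 of them among its 317, under DESeq2, other size factors, no filter, other cell minimums, other classes, and without cells rich in other RNA or between the classes. Calls fell to 150 with thinned cells, 1.1e+02 with no block and 144 with region-day pairs, which tested 270, 208 and 328 genes in place of 1448. Of 339 checks of its 31 named genes, 338 kept direction and side of the threshold and 1, Cxcl1 with other classes, did not pass, though with other classes the log2 difference of Clec4n was 2.01. The genes that made the other classes stayed in that test, so its checks are not independent of them. In the chip test 22 of 73 checks no longer passed (13 of 13 with at least 3 cells, 6 of 14 with no filter), in PVM-like regions 10 of 65, and in microglia-like regions 6 of 191, with 7 newly passing. Of those 191, 12 were with age as a factor, where Amygdala could not be compared. The stage count of 0 became 316 with no filter, 7 with chip pools, 2 with all cells, 10 with matched regions, 9 with the ventral midbrain pool alone and 15 with its chips; leaving out each embryonic pool gave 0 to 0. The chip test called 1227 with no filter, 3 with at least 3 cells and 7 with thinned cells. The region count of 8 became 49 with no filter, 0 with thinned cells, 30 with at least 1 cell and 165 with all cells. Every region with at least 3 pools was taken, so the regions compared depend on the setting. All cells brought in cortex S1 and SN-VTA among others, with mean PVM-like shares per day pool from 22.6% in DentGyr to 85.7% in SN-VTA. Those 165 calls therefore mix class with region. With age as a factor the count was 24. Neither other region had the days of Amygdala, so that setting compared DentGyr with ZonaIncerta alone. Leaving out single Amygdala or ZonaIncerta pools gave 6 to 10, and no DentGyr pool was left out. The age count of 0 became 1 with at least 5 cells and 1 within days 20 to 29. The PVM-like region count of 47 became 16 without cells rich in other RNA and 24 without the other-cell genes. Lists called in the class and stage tests fell from 10 to 4 with an estimated correlation. Where fewer genes tested or other regions compared do not show it, the cause was not tested. The stricter filter removed no tested gene and says nothing. The region test with at least 5 cells per pool and the age test in cortex S1 alone were not run, since too few pools were left. No named gene of the class and chip tests changed direction. The region tests have no direction, and the stage and age tests had no named genes to check. Depth limits the tests to abundant genes, as thinning left 21 to 270.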

Other observations

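All tests below were chosen after the result was seen.

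PVM-like cells differed between 5 postnatal regions, most of all in myelin genes. Mal averaged 5016 CPM ± 3062 (SD, n = 7) in cortex S1 and 7464 ± 6469 (n = 3) in SN-VTA, against 21.5 ± 52.7 (n = 6) in Amygdala and 87.3 ± 151 (n = 3) in DentGyr. All 12 tested oligodendrocyte genes were called, among them Mog, Mobp and Cnp. Cryab, a small heat shock protein, averaged 1555 ± 985 CPM in cortex S1 and had 0 UMIs in Amygdala and DentGyr. Ptgds, a prostaglandin synthase, averaged 5225 ± 5304 CPM in cortex S1 and Car2 2993 ± 1659. Gria1 was highest in Amygdala at 1180.3 ± 521 CPM, and Nnat in the hypothalamus at 1419 ± 1268.

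Some called genes are expressed by macrophages. In the hypothalamus (n = 5), the Fc receptor chain Fcer1g averaged 4239 CPM ± 1894 against 1088 ± 314 in Amygdala, C1qb 5224 ± 1000.2 against 1912 ± 824, the interferon-induced Ifitm3 1480.4 ± 304 against 304 ± 254, and the heat shock gene Hspa1a 2267 ± 1380 against 152 ± 148. The chemokine Ccl2 averaged 7469 ± 2520.1 in SN-VTA and 1301 ± 679 in DentGyr, and Tyrobp 3159 ± 2519.9 and 1218 ± 332. Lyz2 averaged 8523 ± 2766 CPM in cortex S1 and 4238 ± 1576 in DentGyr, and Mef2c 1257 ± 516 in DentGyr and 251 ± 365 in SN-VTA. Of these genes, C1qb, Ifitm3, Ccl2, Tyrobp and Mef2c lost their call without the cells richest in other RNA (edgeR, Benjamini-Hochberg adjusted p = 0.0818, 0.0601, 0.143, 0.0585 and 0.0943). The largest log2 difference between regions went from 2.76 to 2.83 for Ifitm3, 1.63 to 1.54 for Tyrobp, 2.51 to 2.07 for Ccl2, 1.45 to 1.06 for C1qb and 2.56 to 1.95 for Mef2c, so the lost calls do not show where the RNA came from. The dissociation list summed to 23871 ± 9184 CPM in the hypothalamus and 9500 ± 6190 in Amygdala. In total edgeR called 47 of 177 genes at a Benjamini-Hochberg adjusted p under 0.05 (24 pools, 163 cells), 16 without the cells richest in other RNA and 24 without the other-cell genes.

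The difference between the classes was also compared across 5 regions with 21 pairs of one region and one day. With edgeR, 0 of 266 genes differed between regions at a Benjamini-Hochberg adjusted p under 0.05, with 17 at an unadjusted p under 0.05. DESeq2 was not run on this test.

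Chance was tested with 100 splits of each set of pools, the real one included. For the class comparison, 1 of 100 splits gave as many as 317 genes, with a highest other count of 181, and for the ventral midbrain chips 1 of 100 gave 15, with a highest other count of 1. For regions, 2 of 100 splits gave as many as 8 genes in microglia-like cells, the highest other count being 9, and 1 of 100 gave 47 in PVM-like cells, the highest other being 19. Another split called 9 genes, more than the real 8, and the splits moved region while leaving age in place. They therefore do not exclude chance for the region count in microglia-like cells. The classes were made by clustering the same cells and the splits were not clustered again, so the splits do not exclude chance for the class count. The chip test and the test of PVM-like regions were chosen because those groups stood apart, and chips may share animals, so their splits do not exclude chance. For the stage and age counts of 0, 100 of 100 splits give as many by construction, with highest other counts of 3 and 1, so the splits do not test these counts.

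The cells outside the comparisons had these values. In the 2 bone marrow cells, Lyz2 stood at 48575 CPM (Poisson interval 42270 to 55555), and the chemokine receptor Ccr2 at 4561 (2786 to 7044). In the 2 epidermis cells, Mrc1 stood at 1904 CPM (1219.8 to 2833) and Apoe at 14993 (12932 to 17289), and P2ry12 had 0 UMIs. In the 6 brain cells of days 67 to 90, Cx3cr1 stood at 6074 CPM (4463 to 8077) and P2ry12 at 7883 (6030 to 10126). In 6 PVM-like cells of cortex S1 with the embryonic label, Apoe stood at 14060 CPM (12545 to 15707) and F13a1 at 4851 (3979.6 to 5857).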
